A study of Mus musculus with 6 samples.

How the data were processed

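Prostate RNA from 6 male mice aged 30 days was measured on one-colour (Cy3) Agilent arrays, 1 array per animal, with 3 offspring of control dams and 3 offspring of dams given MC-LR in drinking water at 10 μg/L. Per the labels, the offspring of each group came from different dams, so the replicates are separate litters. The labels describe the content of the arrays as piRNA expression.

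The intensity values were made by the authors with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. Per the file headers, the deposited processed intensity of each spot is background-subtracted within its array and is not scaled between arrays. The same deposited files give the spot's median intensity, its local background and 0 or 1 flags for detection, non-uniform spots and saturation. The grid named in the headers refers to the mm9 build, but the files pair no probe with a coordinate, a sequence or a piRNA name. All 41069 non-control probes carry only a manufacturer's number, so probes are named here by that number, and the rule below names at most 2 in each direction. ASPI031935P is named in addition, since it passed the threshold when an array was left out. A further 1417 spots are controls.

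The authors also deposited a table of log2 values for 17220 of these probes. Its normalization and filter are not given in the sources used here. Each of its columns correlated at 0.998 to 1.00 with the log2 processed intensity of its own array, at 0.942 to 0.973 with the closest other array, and at 0.999 to 1.00 with a quantile normalization of the same probes made here. The column medians were between 5.18 and 5.21, so the values are log2 intensities without gene centring. The table holds 3768 probes that were well above background on no array. It was used as an alternative.

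Log2 processed intensities were scaled by subtracting from each array its 75th percentile over the 6913 probes flagged well above background on all 6 arrays, because fewer than 50% of probes were detected on any array. Spots flagged non-uniform were left out, and no spot was saturated. Probes well above background on all arrays of at least 1 group were tested. Of these 8781 probes, 54 were left out because a spot was flagged, and 8727 were tested. Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without covariates), and p-values were adjusted by the Benjamini-Hochberg method over the 8727 probes. All tests were two-sided. Comparisons of single values between the groups used an exact permutation test, whose smallest possible p with 3 arrays in each group is 0.1. That test treats all 6 arrays as exchangeable and ignores the shared scans described below. A test that kept the pairs would have fewer splits and a larger smallest p, and none was run. The precision is limited by the number of arrays.

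Both groups carry replicate numbers 1 to 3. The headers give the 2 arrays with the same number the same scan time, so each scan held 1 control and 1 MC-LR array, the control array always in position 1 and the MC-LR array always in position 2 of the slide. Position and group can therefore not be told apart. Scan 1 was made on another day than scans 2 and 3. Deviations from the group means correlated at 0.50, 0.14 and 0.52 between the arrays of scans 1, 2 and 3. Pairs with unlike numbers were at -0.51 to 0.28, and the highest, control replicate 2 with MC-LR replicate 3, was above the 0.14 of scan 2. The numbers were taken as pairs because of the shared scan times. The fit with the replicate number as a block was an alternative.

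The following choices were made before the data were examined: the test, the scaling, the probe filter, the rule for named probes and most alternatives. The alternatives changed the scaling, the background correction (normexp with an offset of 50 on median and background intensity, since the files used here hold no mean intensity column), the probe filter, the variance model, the block and the test, and left out each array in turn. Alternatives chosen after seeing the data were the authors' table with its own probe set and a comparison without the arrays of scan 1, and the bounds for probes detected on only part of a group's arrays were also added then. The rule for named probes was, with no probe past the adjusted threshold, the smallest unadjusted p in each direction among probes whose groups did not overlap, and separately the 5 probes with the highest mean level. Sets by accession, chromosome, genomic window and sequence had been planned and were not tested, since the files used here do not pair probes with these. Gene lists fixed in advance did not apply, as every non-control probe belongs to the same piRNA series of probe numbers.

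The fit was tested on simulated data that had the real means and spreads of the 8727 probes, effects shared within a scan, and 200 probes changed by a known fold. At an adjusted p under 0.05 it recovered 0% of probes changed 2-fold, 52.5% of those changed 4-fold and 77.5% of those changed 8-fold. With the replicate block it recovered 0%, 62.5% and 82.0%.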

Results

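The series measured PIWI-interacting RNAs (piRNAs), small RNAs best known for silencing transposons in germ cells, in the prostates of young male mice. Dams drank water with 0 or 10 μg/L MC-LR, starting on day 12 of gestation and ending on postnatal day 21, and prostates of their male offspring were taken at 30 days of age. MC-LR is the usual abbreviation of microcystin-LR, a cyanobacterial peptide toxin that inhibits serine/threonine protein phosphatases. The comparison asks how the piRNA profile of the prostate differed after exposure of the dam, between 3 control and 3 MC-LR offspring of different dams.

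Most piRNA probes were not detected in the prostate. Of 41069 probes, 25948 (63.2%) were well above background on none of the 6 arrays, 3157 on a single array and 6913 (16.8%) on all 6. Control prostates had 9904 ± 1240 detected probes (SD, n = 3) and MC-LR prostates 10709 ± 1316 (SD, n = 3), a difference of 805 probes that was within the spread between arrays (exact permutation test, p = 0.6) and ranged from 283 to 1545 when 1 array was left out. With the looser flag for a positive and significant signal, 47.6% ± 0.58 of probes were flagged in control and 51.9% ± 4.18 in MC-LR prostates (SD, n = 3 each). Every MC-LR array was above every control array (exact permutation test, p = 0.1, the smallest this test can give, with the scans ignored). By array, 11326, 9337 and 9049 probes were detected in control replicates 1, 2 and 3, and 11143, 9231 and 11754 in MC-LR replicates 1, 2 and 3. Within scans, the MC-LR array therefore had slightly fewer detected probes than its control in scans 1 and 2 and more in scan 3.

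**Figure D1:**
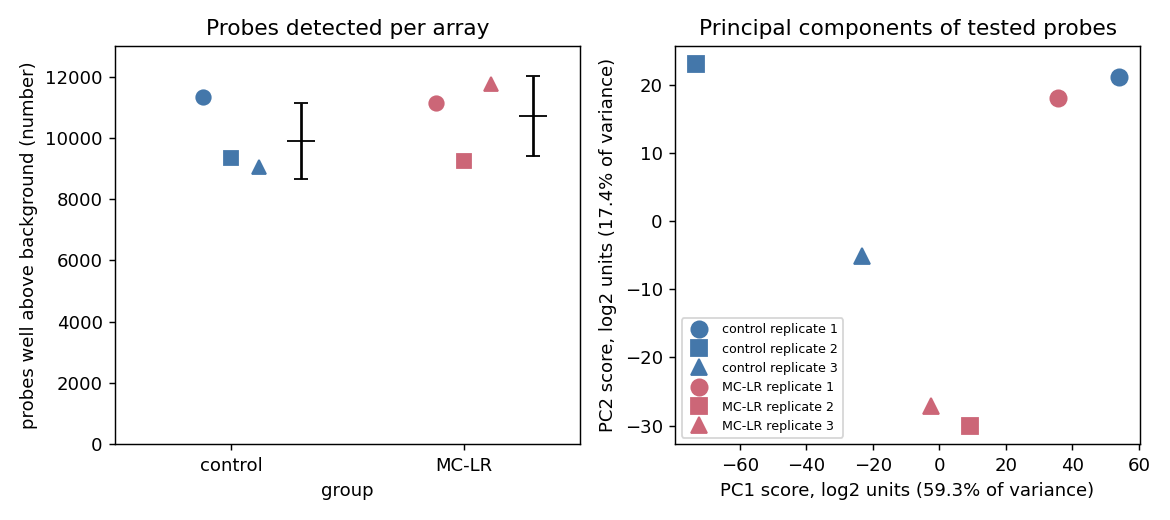
Left, number of probes well above background on each array (circle, square and triangle for replicates 1, 2 and 3, which are also scans 1, 2 and 3), with the group mean and SD beside the points. Right, scores of the 6 arrays on the first 2 principal components of the 8727 tested probes (log2 units). PC1 (59.3% of variance) runs from control replicate 2 at -73.1 to control replicate 1 at 53.9, with the 3 MC-LR arrays between them.

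The signal was concentrated in few probes. The 240 tested probes with a mean log2 intensity above 14 carried 81.2% to 87.1% of the summed intensity of all non-control probes of an array. The brightest probe, ASPI224694P, had an intensity of 358385 ± 100907 (SD, n = 3) in control and 435286 ± 62927 (SD, n = 3) in MC-LR prostates. The next were ASPI287393P with 354424 ± 63846 in control and 367372 ± 23171 in MC-LR, ASPI107239P with 324311 ± 75299 and 366991 ± 49685, ASPI157131P with 336681 ± 69979 and 327838 ± 41686, and ASPI289292P with 307518 ± 72542 and 359481 ± 41782. These 5 probes had log2 changes between -0.07 and 0.27 after scaling, with limma adjusted p-values of 0.997 to 0.999. Over the 240 brightest probes, control replicate 2 had a median deviation after scaling of -0.55 (log2) from the mean of the 6 arrays, the largest of any array. The files used here give no piRNA name for these or any other probes.

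No piRNA probe passed the threshold between MC-LR and control prostates. Of 8727 probes tested with limma, 0 rose and 0 fell at an adjusted p under 0.05, and the smallest adjusted p was 0.961. With the replicate number as a block, which compares the arrays of the same scan, the count was also 0, with a smallest adjusted p of 0.699. Without control replicate 1, limma called 1 probe, ASPI031935P, higher in MC-LR (adjusted p = 0.0245; adjusted p = 0.997 with all arrays). It was well above background in control replicate 1 and not in the other 2 control arrays. There its signals of 5.97 and 4.50 were below the lowest detected signals of 29.8 and 22.4. The same 2 values are the medians over all probes of these arrays and recur as medians of several control spot families. They stand for a floor of the array rather than a level of this probe. The fit without control replicate 1 therefore compares MC-LR with undetected values in the other 2 control arrays. With those 2 arrays set to the lower limit of detected signal, MC-LR was higher than them by at least 1.50 on the log2 scale without overlap. The 3 MC-LR arrays, at -2.17, -2.28 and -1.89, were also above control replicate 1 at -2.70. At an unadjusted p under 0.05, limma without the block gave 114 probes higher and 157 lower, 271 in all (3.1%). An even spread of p-values gives 436. With the block it gave 212 higher and 301 lower, 513 in all (5.9%). The 436 is not a chance number for the fit without the block, since effects shared within a scan lower its count. In the simulated data that fit put 1.8% to 2.0% of unchanged probes under 0.05, and the fit with the block 5.5% to 5.9%. The simulated scan effects had a set size, so these shares are a rough guide. The median log2 change over all tested probes was 0.01 (exact permutation test over the 10 splits of the arrays, p = 0.8).

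The probe with the smallest unadjusted p, ASPI370680P, was 3.02-fold higher in MC-LR prostates, with scaled log2 values of -2.78 ± 0.11 in control and -1.18 ± 0.03 in MC-LR (SD, n = 3 each; log2 change 1.59, SE 0.22, limma adjusted p = 0.961). Within scans 1, 2 and 3 its MC-LR array was higher by 1.49, 1.75 and 1.54 on the log2 scale. The direction in each scan follows from the choice among probes with non-overlapping groups. The second, ASPI179214P, was 3.45-fold higher, at -2.38 ± 0.23 in control and -0.60 ± 0.29 in MC-LR (SD, n = 3 each; log2 change 1.79, SE 0.27, limma adjusted p = 0.961), with within-scan differences of 1.41, 2.35 and 1.60. Among probes lower in MC-LR, ASPI260316P had scaled log2 values of -2.92 ± 0.30 in control (SD, n = 3; limma adjusted p = 0.997). It was well above background on all 3 control arrays and on 1 of the 3 MC-LR arrays, and its signals in MC-LR replicates 2 and 3, 4.09 and 3.67, were below the lowest detected signals of 20.4 and 16.4. The 4.09 is also the median of several control spot families on MC-LR replicate 2, and so a floor of that array. The difference of ASPI260316P is therefore only a bound, with MC-LR lower by at least 1.23 on the log2 scale when MC-LR replicates 2 and 3 are set to the lower limit of detected signal. ASPI008932P was at 0.30 ± 0.37 in control and -0.93 ± 0.08 in MC-LR (SD, n = 3 each; log2 change -1.24, SE 0.27, limma adjusted p = 0.997). These 4 probes were chosen among those with non-overlapping groups, and none passed the adjusted threshold. They were picked for small p-values. With normexp background correction the log2 changes were 0.80, 1.09, -0.61 and -0.94 in this order. That correction adds an offset of 50 to the signals, which makes log2 changes of dim probes smaller. The bound for ASPI260316P applies to values without the offset and cannot be set against the -0.61.

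**Figure D2:**
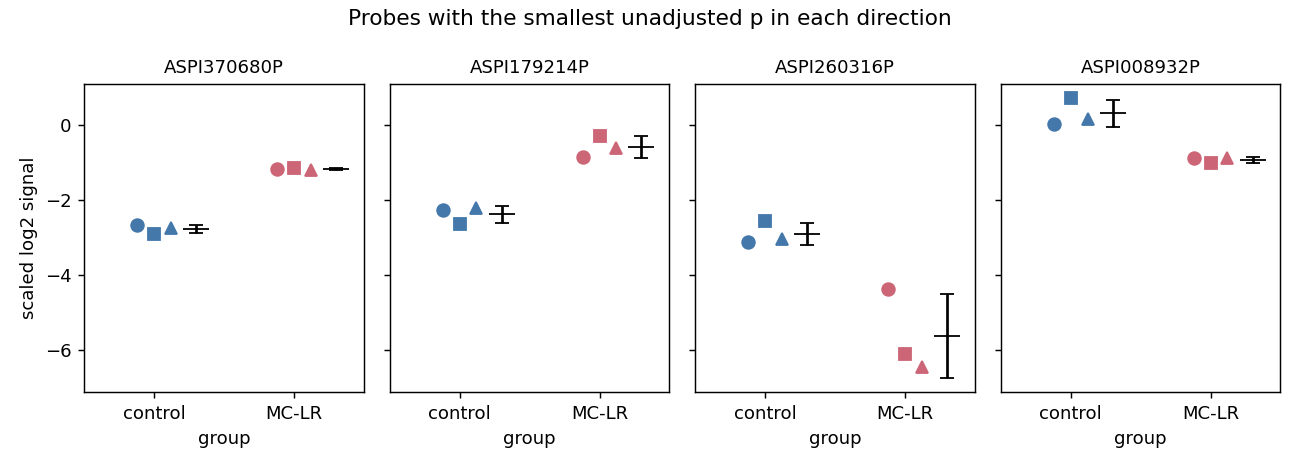
Scaled log2 intensity, per array, of the 2 probes with the smallest unadjusted p in each direction (circle, square and triangle for replicates 1, 2 and 3), with the group mean and SD beside the points. The first 2 panels are the probes higher in MC-LR prostates and the last 2 those lower. In the third panel, MC-LR replicates 2 and 3 were not well above background. The groups do not overlap in any panel, as the choice of probes required, and the adjusted p-values are 0.961 for the first 2 and 0.997 for the last 2.

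A looser threshold of an unadjusted p under 0.05 and at least a 2-fold change was met by 153 probes, 72 higher and 81 lower in MC-LR prostates, before any correction for multiple tests. With the replicate block the number was 197, with 72 higher and 125 lower. Without control replicate 1 it was 1044, without control replicate 3 it was 92 and without MC-LR replicate 2 it was 74. The 3 MC-LR arrays lay all above or all below the 3 control arrays for 696 probes, 315 higher and 381 lower. This is 7.98% of the tested probes, against 10% for exchangeable arrays, a share that effects shared within a scan make smaller. Without scaling between arrays the split was 321 higher and 124 lower, and with quantile normalization it was 395 and 301. Leaving out 1 array gave 1006 (without control replicate 3) to 3308 probes (without control replicate 1), where exchangeable arrays give 1745. The within-scan difference had the same sign in all 3 scans for 2622 probes, 1251 higher and 1371 lower. This is 30.0%, against 25% if the differences of the 3 scans were independent. Across probes they correlated at 0.51 between scans 2 and 3, 0.14 between scans 1 and 3 and -0.24 between scans 1 and 2. The 25% is therefore no chance level for these data. Probes are not independent of each other, so neither share has a test.

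**Figure D3:**
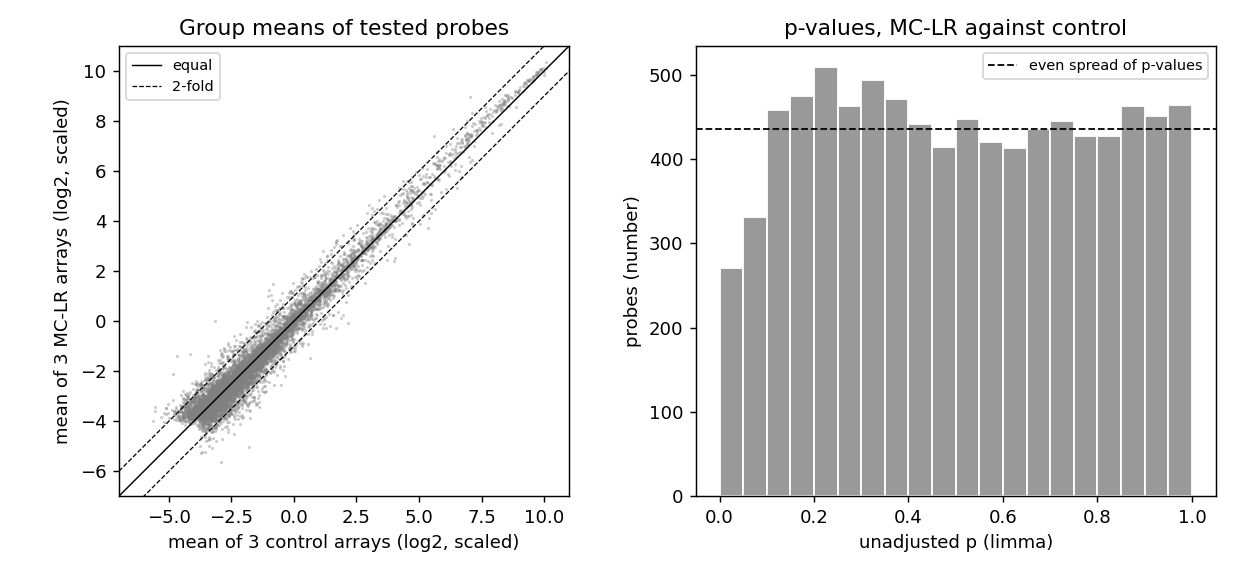
Left, mean scaled log2 intensity of each of the 8727 tested probes in the 3 MC-LR arrays against the 3 control arrays, with lines for equal values and for 2-fold differences. Right, number of probes by unadjusted limma p in steps of 0.05, with a dashed line for an even spread. The lowest step holds 271 probes, against 436 for an even spread, which is not a chance number for this fit without the block.

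Dim, middle and bright piRNA probes were compared as tertiles of the mean level, each of 2909 probes, as a description. The lowest tertile had a median log2 change of 0.01, with 93 probes higher and 145 lower without overlap of the groups. The middle tertile had -0.04, with 77 higher and 138 lower. The highest tertile had 0.06, with 145 higher and 98 lower. In the highest tertile the median within-scan difference was -0.03 in scan 1, 0.16 in scan 2 and 0.05 in scan 3. The sign depended on the scaling for the lowest tertile, at -0.06 with normexp, and for the middle tertile, at 0.05 with quantile normalization, and the highest stayed between 0.03 and 0.12 under the 6 other scalings. No tertile held a probe past the adjusted threshold.

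Few piRNA probes were detected in one group alone. On all 3 MC-LR arrays and no control array there were 37 probes, and on all 3 control arrays and no MC-LR array there were 8. The other 18 ways of drawing 3 of the 6 arrays gave 1 to 518 such probes, with a median of 21. A probe in the undetected group has only a bound, set for each array by the lower limit of detected signal or the probe's own value. The 8 probes seen in control alone were at least 1.46- to 2.46-fold higher in control, and 27 of those seen in MC-LR alone had a bound above 1, up to at least 1.47-fold higher in MC-LR. The limma adjusted p-values of these probes were 0.975 or more.

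The precision of single probes was low. The median SE of a log2 change was 0.34 without the block and 0.23 with the replicate block. Without the block, the median half-width of the 95% interval was 0.81. For 3591 probes (41.1%) the interval lay within a 2-fold change in either direction. In simulated data of this size, with 200 changed probes and errors independent between probes, 2-fold changes were not recovered at the adjusted threshold. At an unadjusted p under 0.05, limma without the block found 68% of them, against 1.9% of the unchanged probes. Under this setting, changes of that size in single piRNAs would be missed at the adjusted threshold. Other numbers of changed probes were not simulated. Pairs of arrays within the control group correlated at 0.854 to 0.948 across tested probes, pairs within the MC-LR group at 0.962 to 0.978, and the 2 arrays of the same scan at 0.976, 0.908 and 0.975 in scans 1, 2 and 3.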

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

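All tests in this part were chosen after the result was seen. Among 16 families of control spots, which are outside the comparison of piRNA probes, 4 had over 50% of their spots well above background. Of these, the ETG05 spots were brighter on every MC-LR array than on every control array, with a median intensity of 115 ± 12.1 against 87.4 ± 4.16 (SD, n = 3 each). The difference was 0.39 in log2 intensity before scaling (exact permutation test, p = 0.1, the smallest this test can give, with the scans ignored). Exchangeable arrays separate the groups in 10% of families, and 4 were looked at. A brighter array as a whole is a candidate explanation. After scaling by the 75th percentile the mean difference was 0.35, the within-scan differences were -0.05, 0.94 and 0.16, and the groups overlapped (exact permutation test, p = 0.3), so the spread is too large to exclude it. Among the same 4 families, the GE_BrightCorner spots overlapped between the groups before scaling. After scaling they were higher on the MC-LR array within each scan, by 0.23, 0.76 and 0.92. The DCP_22 spots differed by -0.18, -0.04 and -0.16, and the DCP_20 spots by -0.25, 0.49 and -0.02. Position on the slide goes with the group, so an effect of position cannot be told apart. What the ETG05 spots hybridise to is not given in the sources used here, and no biological explanation was tested.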

How the results depend on the processing

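The count of 0 probes past the adjusted threshold was obtained under 22 of 23 alternatives, with smallest adjusted p-values from 0.0245 to 1.00; leaving out 1 array gave 0 to 1. The exception was 1 probe without control replicate 1, ASPI031935P, named after its value was seen (limma adjusted p = 0.0245 against 0.997 with all arrays). The 2 control arrays left were not well above background for it (signals 5.97 and 4.50, the floor of those arrays). The 153 probes at an unadjusted p under 0.05 and 2-fold became 40 with normexp (26 higher, 14 lower), 86 for probes detected on all 6 arrays, 508 without a filter (182 higher, 326 lower), 293 with array weights, whose estimate stopped short of its tolerance, 237 with scan day as a block (80 higher, 157 lower), 79 with a plain t-test and 74 to 1044 when 1 array was left out, with 126 higher and 59 lower without control replicate 2 but 45 and 82 without MC-LR replicate 3. Without scan 1 they became 841, or 942 with the replicate block. The 696 probes with non-overlapping groups became 445 without scaling (321 higher, 124 lower), 1957 without a filter (552 higher, 1405 lower), and 1070 in the authors' table with its own probes; normexp gave 182 higher and 363 lower. Fewer arrays raise this count by construction: 1006 to 3308 with 1 array left out (423 higher and 694 lower without MC-LR replicate 3), where exchangeable arrays give 1745, and 4482 without scan 1, where they give 2909. The median log2 change of 0.01 was 0.064 with the percentile over all probes, 0.066 with quantile normalization or scaling to the median, -0.040 with normexp, -0.184 without a filter and -0.024 to 0.060 when 1 array was left out. Without a filter, most of the probes were well above background on no array. The replicate block changed no call at the adjusted threshold, where it gave 0 probes. At the looser threshold it moved the count from 153 to 197 (72 higher, 125 lower). The difference of 805 detected probes was 1769 with the other detection flag (exact permutation test, p = 0.1, against 0.6) and ranged from 283 to 1545 probes when 1 array was left out. The 4 named probes kept their sign under every alternative that tested them, with adjusted p-values of 0.105 or more. Most alternatives could not have reversed it. The probes were picked for non-overlapping groups, so leaving out arrays keeps the sign, and a change of filter, block or test keeps the log2 change. With normexp ASPI370680P moved from 1.59 to 0.80 and ASPI179214P from 1.79 to 1.09. ASPI260316P, not well above background on 2 MC-LR arrays, moved from a fitted -2.72 to -0.61. The normexp setting adds an offset of 50 to the signals, which by itself makes log2 changes of dim probes smaller. Signals before it were 3.67 to 63.8 for ASPI260316P, 38.9 to 179 for ASPI370680P and 55.8 to 229 for ASPI179214P. The brighter ASPI008932P, at 139 to 627, moved less, from -1.24 to -0.94. Normexp without the offset was not run, so the share of the offset is not known. The causes of the other changes were not tested.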

Other observations

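The tests of the brightness trend in the scans and of the splits for the brightest probes and for the looser threshold were set before their results were seen, and the others in this part after.

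The 240 brightest piRNA probes, those with a mean log2 intensity above 14, were on balance higher in MC-LR prostates, with a median log2 change of 0.32 and 215 of 240 above 0, while the other 8487 tested probes had a median of 0.00. None of the 240 passed the adjusted threshold, and 29 were higher and 6 lower without overlap of the groups. The shift depended on the normalization: it was 0.02 with quantile normalization, which equalises the brightness distributions by construction, 0.01 in the authors' table and 0.33 to 0.37 under the 4 other scalings. The normalization of the authors' table is not given. Its columns share a maximum of 18.6 and correlate at 0.999 to 1.00 with a quantile normalization, so its value is not a separate case. A low value of 1 array over these probes is a candidate explanation. After scaling, control replicate 2 had a median deviation of -0.55 (log2) from the mean of the 6 arrays over these probes. It was not dim as a whole, as its 75th percentile of detected signal was 380, against 261 in control replicate 3. Without control replicate 2 the median change was 0.10, close to but not under the 0.1 that was set as the limit. Leaving out each other array gave 0.26 to 0.49, the highest without control replicate 1, so the size of the shift rests on single control arrays. The shift was not seen in every scan, as the median differences were 0.78 in scan 2 and 0.28 in scan 3 but -0.12 in scan 1. Each scan holds only 1 pair of animals, so an exposure effect is neither shown nor excluded. Nor can it be told apart from an effect of position on the slide, which goes with the group. Of the 10 splits of the arrays, 3 gave a median as large, up to 0.38, and 10 splits are too few for a share under 0.05.

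Differences between the MC-LR and the control array correlated across probes at 0.51 between scans 2 and 3, which were made on the same day, at 0.14 between scans 1 and 3 and at -0.24 between scans 1 and 2. Probes are not independent replicates, and no p-value was computed. A trend with brightness does not account for this as a whole, since removing it from each scan left the correlation of scans 2 and 3 at 0.50, and the authors' table also gave 0.50. An exposure difference shared by all 3 pairs of litters would give 3 positive correlations, and the lowest was -0.24, but each rests on a single pair of animals, so it may still be present in part. Day of scan, the dissection of the prostates and differences between litters stay open as untested. Position on the slide goes with the group in every scan and cannot be told apart from it.

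If neighbouring probe numbers marked related piRNAs, their changes would be expected to correlate. Over 351 pairs of tested probes whose numbers differ by at most 2, the correlation of the log2 change was -0.041 (permutation test, p = 0.449), and the number of pairs is too small to exclude a weak relation.

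The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 probes past the adjusted threshold, as did all 10 splits (highest other 0). For 153 probes at the looser threshold, 5 splits gave as many and the highest other gave 940. For 696 non-overlapping probes, 6 splits gave as many and the highest other gave 2417. For the size of the median change, 0.01, 8 splits gave as large a value, up to 0.08. The split with the highest counts set control replicate 1 and MC-LR replicates 1 and 2 against the rest, keeping the arrays of scan 1 together, and had 1895 probes at an unadjusted p under 0.05, several times the 271 of the real split, which points to a structure of the samples other than the groups. Of the 4 splits that part all 3 scans, the real one had the most probes at the looser threshold, 153 against 5, 58 and 105, but not the most non-overlapping probes, 696 against 88, 325 and 843, nor the most at an unadjusted p under 0.05 with the block, 513 against 37, 174 and 642. The other 6 splits, with the 940 among them, keep the arrays of 2 scans together and are no null for pairs.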
